A study of Mus musculus with 18 samples.

How the data were processed

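ChIP-seq libraries of iHep cells were analysed from the peak lists deposited by the authors. The series as used here holds 18 samples, 9 ChIP libraries and 9 inputs, and a peak list was used for each ChIP library; the input libraries themselves were not analysed here. Cells came from embryos of 13.5 days post coitum, per the labels' protocols. The submitters' processing notes name BWA 0.6.2, MACS2 2.1.0 and bedtools 2.16.2 and the genome build mm9. The settings of the peak caller, its filters and the way the input was used are not given in the sources used here. Each deposited file lists, without a header, the chromosome, start, end and name of each peak and a score. The kind of the deposited score is not given in the sources used here; all scores were above 5 (lowest 5.11). Scores were used only to rank or filter peaks. The narrowest peak differed between lists (242 to 325 bp in the 8 Foxa lists), so widths depend in part on a setting of the caller or on fragment length in each library.

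Starts were converted to count from 1 for printing. On 8 of the 20 chromosomes the furthest peak lies beyond the last gene end of the GRCm38 gene table at hand, and mm9 and GRCm38 coordinates were not mixed. For this reason the planned analyses of peak positions relative to genes, of the 11 gene lists fixed in advance (liver, epithelial, intestinal, fibroblast, housekeeping and other cell types) and of exons of the introduced factors were not run, and no gene is named. The rule for named items was for this case the 5 highest-scoring peaks of each library and the 10 regions of all 8 lists with the best mean rank. Other positions were chosen after seeing the data, as stated beside them.

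Constructs were grouped by the labels into 3 balanced factors with 4 constructs on each side: origin of the DNA-binding domain, terminal layout (Foxa3 domain at the N or the C terminus) and partner protein (Foxa1 or Foxa2). The tests, the rule for named items and the alternatives were fixed before the data were examined. Log2 peak number and median width were compared by exact two-sided permutation over the 70 splits of 8 constructs, whose smallest p is 0.0286, and by an exact sign-flip over 4 matched pairs. Nothing in the labels gives replicate cultures, so p-values measure the spread between single libraries of different constructs. Overlap required 1 bp. Pairs of lists were compared by the share of the shorter list that met the longer one, with 95% Wilson intervals, against 100 random placements on the same chromosomes. The Jaccard index used the 956 strongest peaks of each list, the length of the shortest, to equalise list length. Its mean within against between classes was tested over every assignment of the 8 construct labels (40320 orders, which give 35 distinct splits), one-sided, with Benjamini-Hochberg adjustment over the 3 factors. Regions were made by merging overlapping peaks of the 8 lists.

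Alternatives were a stricter score (above 19.2, the median over the pooled 8 lists), merging of peaks within 1 kb, reciprocal 50% overlap, midpoints within 200 bp, all peaks or the strongest 478 in place of 956, and leaving out each construct in turn. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap routine gave the same counts as bedtools 2.31.1 in all 28 pairs. In tests on simulated data, sets of 8 lists of 956 peaks were made with and without 200 planted regions per terminal class. The terminal split gave an unadjusted p under 0.05 in 100 of 100 sets with planted regions and in 6 of 100 without. The DNA-binding domain and partner splits did so in 0 of the planted sets, an outcome fixed in advance. Only the highest of the 35 splits can fall under 0.05, and the terminal split took that place in every planted set. The simulated lists were random draws of regions without scores and without differences in depth or antibody. These rates therefore do not cover such effects. The exact test of 4 against 4 called 96 of 100 simulated differences of 4 SD and 5 of 100 sets with none.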

Results

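Binding of domain-swapped Foxa proteins was mapped by chromatin immunoprecipitation sequencing (ChIP-seq) in induced hepatocyte-like (iHep) cells. These cells are mouse embryonic fibroblasts turned toward a liver-cell state by forced expression of Hnf4alpha, a liver nuclear receptor, together with a Foxa protein. Foxa1, Foxa2 and Foxa3 are forkhead transcription factors that share a conserved DNA-binding domain flanked by an N-terminal and a C-terminal domain. In 8 constructs one terminal domain of Foxa1 or Foxa2 was exchanged with that of Foxa3, or the reverse. The construct of Foxa1 with the N-terminal domain of Foxa3 is called Foxa1-N3 here, and the others are named likewise. Each construct had 1 ChIP library, so no value below has a replicate, and tests used the constructs as units. The antibody followed the N-terminal domain in all 8 libraries, and the Foxa3 terminal domain sat at either the N or the C terminus. Constructs with the Foxa3 N-terminal domain therefore differed from those with the Foxa3 C-terminal domain in both terminal domains and in the antibody, whereas the DNA-binding domain was balanced over them. A further library, titled 4a3_DA1, carries conflicting labels and is described last. Sequencing depth is unknown, because the deposited files list peaks and not reads. Positions are on mm9, and peaks were not assigned to genes because the gene table used here is on another build.

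The sites of the 5 strongest peaks of each library were common to all constructs. These peaks, 40 in all, fell into 16 regions, and all 16 regions carried a peak in every one of the 8 lists. This did not hold for every strong peak below them. The Foxa3-C1 peak of rank 12 on chromosome 11 (101502730 to 101503829), chosen after its value was seen, was found in 4 of the 8 lists. The peak of rank 2 of the 4a3_DA1 library, whose labels name an Hnf4alpha antibody, lay inside it (101502891 to 101503063). Its absence from some lists is therefore not clearly a difference in Foxa binding. A region on chromosome 17 (35848385 to 35849167) was among the 5 strongest of 7 libraries, with authors' scores from 102.3 to 369.7; in the remaining library, Foxa3-N2, it ranked 310. Regions on chromosome 14 (47449566 to 47450520) and chromosome 4 (3734061 to 3734959) were each among the 5 strongest of 5 libraries, namely Foxa1-N3, Foxa1-C3, Foxa2-N3, Foxa3-C1 and Foxa3-C2. In Foxa3-N2 these regions ranked 497 and 598. Another region on chromosome 14 (100044840 to 100046154) had the best mean rank of all, 8.25, and ranked 29 or better in every library. It was followed by regions on chromosome 3 (113242292 to 113243256; mean rank 14) and chromosome 4 (56114986 to 56115750; mean rank 18.4). The other regions among the 10 with the best mean rank lay on chromosome 9 (61751839 to 61752558), chromosome 6 (31456370 to 31457135), chromosome 1 (87706987 to 87708019 and 75334241 to 75334981), chromosome 3 (133906121 to 133906975), chromosome 17 (the region named first) and chromosome 11 (20979158 to 20980484).

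Most regions carried a peak in few of the lists, which differed widely in length. Merging overlapping peaks of the 8 lists gave 24999 regions, of which 11883 (47.5%) were found in 1 list, 5225 in 2 lists and 529 (2.12%) in all 8. The number of peaks ran from 956 in Foxa1-N3 to 16543 in Foxa3-N2. Foxa2-C3 had 13715 peaks, Foxa3-N1 7625, Foxa3-C1 7533, Foxa2-N3 5230, Foxa1-C3 4807 and Foxa3-C2 3594. Short lists consisted mostly of sites that other constructs also bound: 99.1% of the Foxa1-N3 peaks met a peak of another construct (95% Wilson interval 98.2 to 99.5%), against 64.7% of the Foxa3-N2 peaks (64.0 to 65.5%). Foxa3-N2 alone held 5833 peaks found in no other list. Median peak width ran from 307 bp in Foxa1-N3 to 462 bp in Foxa2-C3, and the narrowest peak in a list from 242 to 325 bp. All intervals given here cover counting error only.

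**Figure D1:**
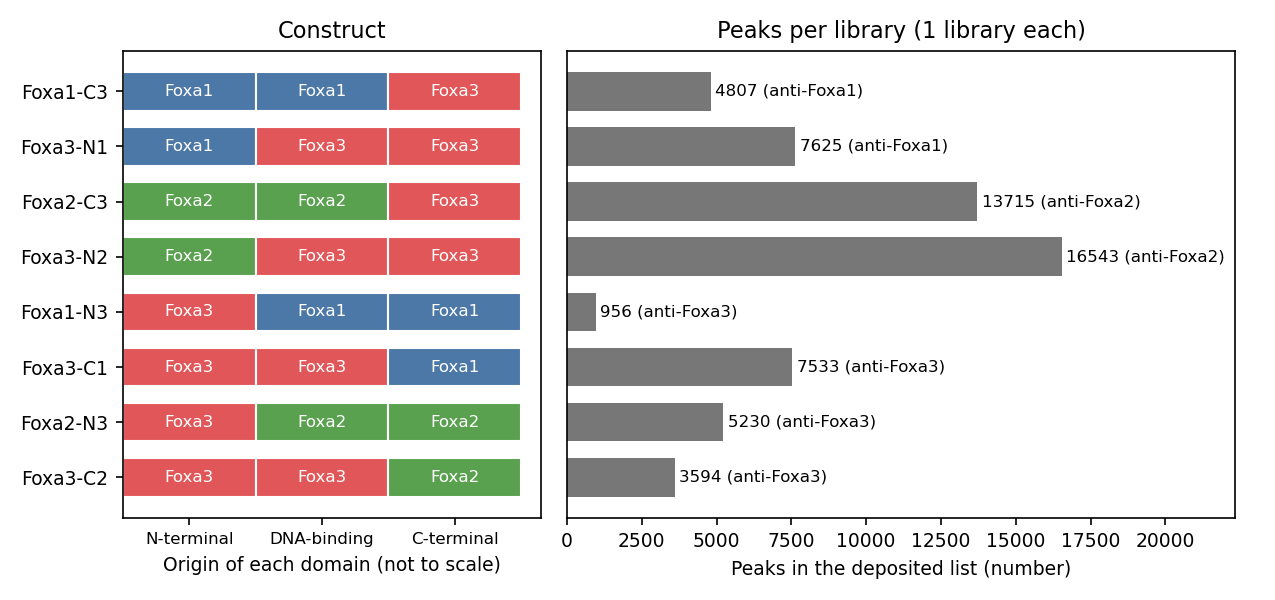
Left, the origin of the N-terminal, DNA-binding and C-terminal domain of each construct (blue Foxa1, green Foxa2, red Foxa3; not to scale); right, bars giving the number of peaks in the deposited list of its single library, with the antibody. Lists run from 956 peaks (Foxa1-N3) to 16543 (Foxa3-N2).

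The first comparison asked what the DNA-binding domain contributed when the terminal domains and the antibody were held fixed. Foxa1-C3 and Foxa3-N1, both carrying the Foxa1 N-terminal and the Foxa3 C-terminal domain, shared 3179 peaks, 66.1% of the Foxa1-C3 list (64.8 to 67.5%) and 41.7% of the Foxa3-N1 list (40.6 to 42.8%). Foxa2-C3 and Foxa3-N2 shared 67.7% of the Foxa2-C3 peaks (66.9 to 68.5%) and 56.3% of the Foxa3-N2 peaks (55.5 to 57.0%). Foxa1-N3 shared 90.5% of its 956 peaks (88.5 to 92.2%) with Foxa3-C1, which had 7.88 times as many peaks and shared 11.5% of them (10.8 to 12.2%). Foxa2-N3 and Foxa3-C2 shared 66.5% of the Foxa3-C2 peaks (64.9 to 68.0%) and 45.7% of the Foxa2-N3 peaks (44.4 to 47.1%). Randomly placed peaks met the other list in 0.186 to 0.591% of cases on average in these pairs. The 956 strongest peaks of Foxa2-C3 and Foxa3-N2, the longest lists, were nearly all present in the other full list, with 1.88% and 1.46% missing. More were missing in the other pairs: 6.17% of Foxa1-C3 and 15.6% of Foxa3-N1, and 13.8% of Foxa2-N3 and 9.83% of Foxa3-C2. For Foxa1-N3 and Foxa3-C1 the shares missing were 9.52% and 55.2%, the latter against a list of 956 peaks.

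Some peaks of one list in a pair had no counterpart in the other, each seen in 1 library against 1. Foxa3-N1 had a peak on chromosome 16 (62418428 to 62418997; score 218.8, rank 42) with no counterpart in Foxa1-C3, found in 2 of the 8 lists. Foxa2-C3 had one on chromosome 6 (39046885 to 39047584; rank 171) with none in Foxa3-N2. Across all constructs, 14 regions were present in all 4 lists with the Foxa3 DNA-binding domain and in none of the 4 with that of Foxa1 or Foxa2, and 0 regions showed the reverse. The direction turned when the short Foxa1-N3 list was left out and the other lists were limited to their 3594 strongest peaks, with 6 and 24 regions. The side of Foxa1 or Foxa2 then held fewer lists than the other, so presence in fewer lists was enough to count there. Neither direction can therefore be taken from these counts. The region with the best mean rank among these 14 lay on chromosome 2 (69381382 to 69382113). The peaks named in this paragraph were chosen after their values were seen, and 20 of the 35 ways to split the 8 libraries into 4 and 4 gave at least 14 such regions.

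Constructs with the Foxa3 DNA-binding domain had a geometric mean of 1.79 times as many peaks as those with the domain of Foxa1 or Foxa2 (log2 number of peaks 12.90 ± 0.90 against 12.06 ± 1.59, SD, n = 4 constructs each). The difference lay within the spread between constructs (exact two-sided permutation p = 0.429, adjusted p = 0.643 over 6 tests of number and width), and without Foxa1-N3 the log2 difference was 0.12 in place of 0.84. In the matched pairs the Foxa3 domain gave more peaks in 3 of 4 (exact sign-flip p = 0.375, where 0.125 is the smallest that 4 pairs allow). Median widths of 411.5 ± 38.6 and 397.3 ± 65.0 bp did not differ beyond that spread either (exact permutation p = 0.714, n = 4 each), and the sign of this width difference turned when Foxa1-N3 (-15.8 bp) or Foxa3-C1 (-0.25 bp) was left out.

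The second comparison set constructs with the Foxa3 N-terminal domain (Foxa1-N3, Foxa2-N3, Foxa3-C1, Foxa3-C2; Foxa3 antibody) against those with the Foxa3 C-terminal domain (Foxa1-C3, Foxa2-C3, Foxa3-N1, Foxa3-N2; Foxa1 or Foxa2 antibody). In each of the 4 pairs matched on DNA-binding domain and partner protein, the construct with the Foxa3 C-terminal domain had more peaks. In 1 pair this was a near tie, with 7625 peaks in Foxa3-N1 and 7533 in Foxa3-C1. The geometric mean with the Foxa3 C-terminal domain was 2.8 times that of the others. Log2 numbers were 11.74 ± 1.30 and 13.22 ± 0.81 (SD, n = 4 each; exact two-sided permutation p = 0.114, adjusted p = 0.6), and without Foxa1-N3 their difference was -0.87 in place of -1.49. With peaks above the pooled median score it was -2.14 (exact permutation p = 0.0571). The sign-flip test over the pairs reached its smallest possible value (exact p = 0.125). Median widths were 382.5 ± 63.3 and 426.3 ± 23.9 bp (exact permutation p = 0.200, n = 4 each). The difference of -43.75 bp depended on single constructs: it was -18.6 bp without Foxa1-N3 (exact permutation p = 0.4) and -67.9 bp without Foxa3-C1 (exact permutation p = 0.0286, unadjusted and the smallest possible).

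Some regions carried peaks on one terminal side alone. In total 304 regions were present in all 4 lists with the Foxa3 C-terminal domain and in none with the Foxa3 N-terminal domain, and 6 regions showed the reverse. Of the 35 splits of the 8 libraries, 1 gave as many in both directions together (310; highest other 241; adjusted exact permutation p = 0.0857), and 3 did without Foxa1-N3. The regions of the first kind with the best mean rank lay on chromosome 6 (41450794 to 41451373), chromosome 2 (179503649 to 179504248) and chromosome 19 (4484988 to 4485545), the last ranking between 42 and 3108. The regions of the second kind with the best mean rank were neighbours on chromosome 11 (87239944 to 87240849 and 87275526 to 87276480), ranking between 50 and 847, followed by one on chromosome 7 (33478378 to 33479156). These regions were chosen after their values were seen. The excess on the C-terminal side was seen with lists of unequal length: with the 956 strongest peaks of each of the 8 lists, 20 regions were specific to the Foxa3 C-terminal domain and 21 to the Foxa3 N-terminal domain. With all peaks and without Foxa1-N3 the numbers were 311 and 81, and with the 3594 strongest peaks and without Foxa1-N3 they were 78 and 156. In both runs the Foxa3 N-terminal side held 3 lists against 4, so presence in fewer lists was enough to count there. With Foxa1-C3 left out as well, 3 lists against 3 with 3594 peaks each, the numbers were 126 and 192.

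The partner protein was the third factor. Constructs made of Foxa2 and Foxa3 had a geometric mean of 2.0 times as many peaks as those made of Foxa1 and Foxa3, with log2 numbers of 12.98 ± 1.07 and 11.98 ± 1.42 (SD, n = 4 each). The difference lay within the spread between constructs (exact permutation p = 0.314, adjusted p = 0.629), and it was positive in 3 of 4 matched pairs. Without Foxa1-N3 the log2 difference was 0.31. Foxa3-C1 and Foxa3-C2 differ in the origin of the C-terminal domain alone and were mapped with the same antibody. They had the most similar strongest peaks of all 28 pairs, with 592 of the 956 strongest shared (Jaccard index 0.448). Of the Foxa3-C2 peaks, 82.9% (81.6 to 84.1%) met a Foxa3-C1 peak, whereas 39.4% (38.3 to 40.5%) of the longer Foxa3-C1 list met a Foxa3-C2 peak. The strongest Foxa3-C1 peak with no counterpart lay on chromosome 12 (35239610 to 35240331; rank 115), and the strongest such Foxa3-C2 peak on chromosome 18 (56194791 to 56195188; rank 343).

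To ask which domain made binding alike, the 956 strongest peaks of each list were compared by the Jaccard index, the number of shared peaks divided by the number in either list. Over the 28 pairs the index had a median of 0.318 and ran from 0.194 to 0.448. The 4 pairs with the highest index all shared the terminal layout: Foxa3-C1 with Foxa3-C2, Foxa1-C3 with Foxa2-C3 (0.412), Foxa2-C3 with Foxa3-N2 (0.400) and Foxa2-N3 with Foxa3-C2 (0.395). The next highest index, 0.383, belonged to Foxa2-N3 with Foxa3-N1, which differ in layout, DNA-binding domain, partner and antibody. Foxa1-N3 was closer to Foxa3-N1 of the other layout (0.344) than to Foxa3-C1 (0.289) or Foxa3-C2 (0.304) of its own. Its index with Foxa2-N3, also of its own layout, was 0.346. The lowest values, 0.194, belonged to Foxa3-N2 with Foxa3-C1 and with Foxa1-N3. The mean index was 0.357 in the 12 pairs with the same terminal layout and 0.285 in the 16 others. This difference was the largest of the 35 possible splits of the 8 libraries (exact permutation p = 0.0286, one-sided, the smallest the design allows; adjusted p = 0.0857 over the 3 factors, so it did not pass 0.05 after adjustment). It was the second largest when Foxa1-N3, Foxa3-C1 or Foxa3-C2 was left out. Pairs with the same class of DNA-binding domain had a mean index of 0.309 against 0.322 for the others (exact permutation p = 0.657), and pairs with the same partner 0.312 against 0.320 (exact permutation p = 0.486). The 4 pairs that differ in the DNA-binding domain alone had an index of 0.361 ± 0.051 (SD over pairs).

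**Figure D2:**
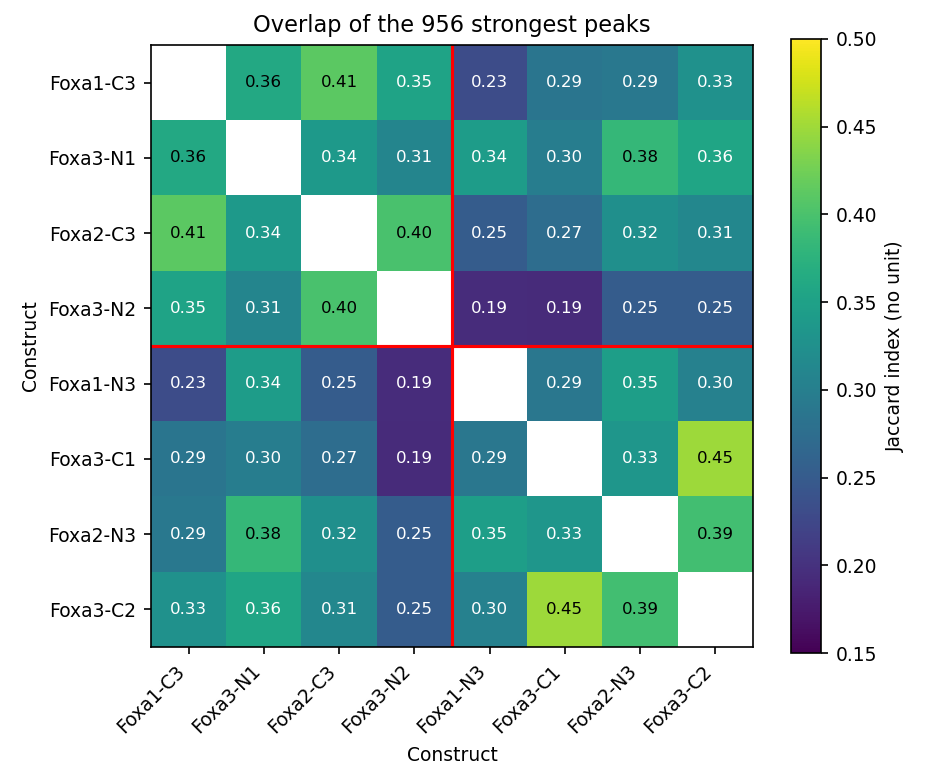
Heat map of the Jaccard index (no unit, colour scale and printed values) between the 956 strongest peaks of each pair of constructs; both axes list the constructs, and red lines part the 4 with the Foxa3 C-terminal domain (first) from the 4 with the Foxa3 N-terminal domain. The mean is 0.357 within the blocks on the diagonal and 0.285 outside them.

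The library titled 4a3_DA1 gave another kind of list. Its title names a Foxa3 construct, while its other labels name Foxa1 with Hnf4alpha and an Hnf4alpha antibody, so it entered no domain comparison. It had 698 peaks with a median width of 115 bp (narrowest 83 bp), and 33.5% of them lay within 1 kb of the preceding peak, against 0.523 to 4.90% in the other 8 lists. Its peaks met those of Foxa3-C1 most often (226 peaks, 32.4%; 29.0 to 35.9%), then Foxa3-C2 (17.2%), Foxa3-N2 (15.2%), Foxa2-N3 (12.6%), Foxa2-C3 (7.88%), Foxa3-N1 (3.87%), and Foxa1-N3 and Foxa1-C3 (1.58% each). This order depended on list length: the 956 strongest peaks met 60 of its peaks in Foxa3-C1, 52 in Foxa3-C2, 27 in Foxa2-N3, 15 in Foxa3-N2, 11 in Foxa1-N3, 10 in Foxa2-C3, 7 in Foxa3-N1 and 5 in Foxa1-C3. Randomly placed, the 4a3_DA1 peaks met each list in 0.0272 to 0.404% of cases, but such placement does not keep their clustering and is a low bar. The 226 peaks that met Foxa3-C1 fell on 165 of its peaks, so they were not all separate sites. In 9 windows of 1 Mb that held at least 10 of its peaks each, 124 of its peaks (17.8%) were found. These windows, defined after the data were seen, included chromosome 19 from 5 to 6 Mb, chromosome 3 from 96 to 97 Mb, chromosome 11 from 101 to 102 Mb and chromosome 13 from 23 to 24 Mb. The 2 widest peaks of the Foxa libraries lay in the chromosome 19 window, at 6164 bp in Foxa3-C1 (5839516 to 5845679) and 5032 bp in Foxa3-C2 (5840662 to 5845693). The widest Foxa2-N3 peak, 2440 bp, lay there as well (5841142 to 5843581), whereas that of Foxa3-N2, 2801 bp, lay on chromosome 9 (3035566 to 3038366). Of the 99 Foxa3-C1 peaks wider than 1000 bp, 37.4% met a 4a3_DA1 peak, against 1.72% of the narrower ones. In Foxa3-C2 the shares were 60% of 15 wide peaks and 2.29% of the others. The lists with the most wide peaks had lower shares, 1.90% of 105 in Foxa2-C3 and 5.66% of 106 in Foxa3-N2. That chromosome 19 window held 16 peaks of Foxa3-C1, 13 of Foxa3-N2, 8 of Foxa2-C3, 6 each of Foxa3-C2 and Foxa2-N3, and 0 of Foxa1-N3, Foxa1-C3 and Foxa3-N1. The share of a list inside the 9 windows averaged 1.31 ± 0.594% with the Foxa3 N-terminal domain and 0.610 ± 0.214% with the Foxa3 C-terminal domain (SD, n = 4 each; exact two-sided permutation p = 0.0857, adjusted p = 0.257 over 6 tests). Foxa1-N3, with 5 peaks in the windows (0.523%), had the lowest share on its side. It lay above its matched construct Foxa1-C3 (0.374%), but with overlapping Wilson intervals. Leaving out each construct in turn gave an unadjusted exact permutation p from 0.0286, the smallest possible and reached only without Foxa1-N3, to 0.171. Among the 956 strongest peaks of each list the share was 2.51% in both Foxa3-C1 and Foxa3-C2, 0.732% in Foxa2-N3 and 0.209 to 0.628% in the other constructs (exact permutation p = 0.114 by terminal layout, n = 4 each).

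**Figure D3:**
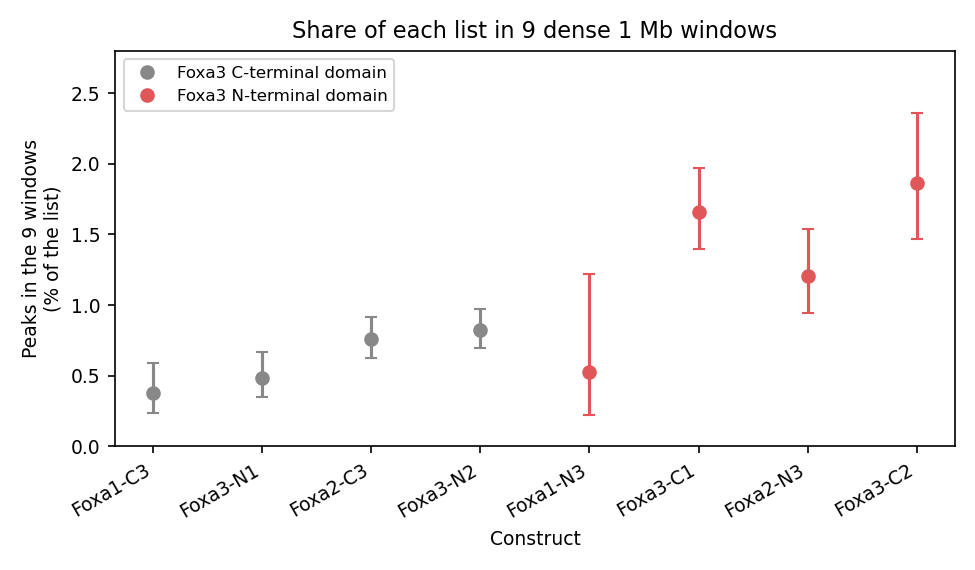
Points give the share (%) of each construct's peaks that lay in the 9 windows of 1 Mb dense in peaks of the 4a3_DA1 library, with 95% Wilson intervals as bars; constructs are on the horizontal axis, grey with the Foxa3 C-terminal and red with the Foxa3 N-terminal domain. Foxa3-C2 (1.86%), Foxa3-C1 (1.66%) and Foxa2-N3 (1.20%) lie above the others, which run from 0.374 to 0.822%.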

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

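The tests of explanations in this part were chosen after the data were seen, although the correction for list length and the rank test of the shortest list were set before their own results.

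In the 4a3_DA1 library, 226 peaks met 165 peaks of Foxa3-C1. This was flagged because the library entered no comparison. Its randomly placed peaks met that list in 0.196% of cases, but random placement does not keep their clustering and is a low bar. A candidate source is chromatin that any antibody enriches. The constructs with the Foxa3 C-terminal domain held 0.610% of their peaks in the 9 dense windows, against 1.31% in the others. The exact permutation test over 8 libraries does not separate this gap from chance (p = 0.0857). By count, the windows held 136 peaks of Foxa3-N2, 104 of Foxa2-C3, 37 of Foxa3-N1 and 18 of Foxa1-C3. On the other side they held 125 of Foxa3-C1, 67 of Foxa3-C2, 63 of Foxa2-N3 and 5 of Foxa1-N3. No background share of the windows was computed, so these values cannot decide it. Longer lists reaching more weak sites would raise the share on the Foxa3 C-terminal side, whose lists were longer. With lists of equal length the gap was 1.15 percentage points, which rested on Foxa3-C1 and Foxa3-C2 and did not pass the test (exact permutation p = 0.114). A wrong label remains possible, and the overlaps cannot decide it: 11 peaks of this library met Foxa1-C3 and 11 met Foxa1-N3. Its labels name an Hnf4alpha antibody, which none of the Foxa libraries used, so its peaks need not match any construct. No library of an unswapped factor was used here. Among the 8 Foxa lists, a difference due to the terminal domains or the antibody stays open and untested, since the antibody follows the N-terminal domain.

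The strongest peaks were more alike between constructs with the same terminal layout. Only 1 of the 35 splits of the 8 libraries, the real one, gave a difference in mean Jaccard index as large (0.072; highest other 0.040), but chance cannot be excluded after adjustment over 3 factors (0.0857), nor without Foxa1-N3, Foxa3-C1 or Foxa3-C2, where 2 of 35 splits were as large. The difference was 0.065, again the highest of the splits (highest other 0.038), after the trend of the index on the gap in list length was removed. The trend on that gap alone thus did not account for it. Depth is unknown and the layout goes with list length, so depth or yield may still have changed which peaks ranked highest. The antibody cannot be told apart from the domains: the 4 pairs with the same layout and different antibodies had a mean index of 0.353 (0.309 to 0.412), above the mean of pairs with different layouts (0.285) but within their range (0.194 to 0.383). A biological difference between terminal domains remains a hypothesis that this layout leaves untested.

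Foxa1-N3 gave the shortest list, 956 peaks, while 99.1% of its peaks met another list. Its counterparts in the other 7 lists lay at a median percentile of 12.8 from the top of the score ranks. The 956 strongest peaks of the other constructs gave 99.0 to 99.9% and percentiles of 9.06 to 15.6, so neither value sets this list apart from a longer list cut to its length. A lower yield of the same sites may account for that, through depth, antibody efficiency or protein level. A weaker binding of this construct is equally open, as no depth is at hand.

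Of 30 groups of 4 constructs examined for a single outlying value, 4 held one; chance gives about 1 in 20 independent groups, but these groups reuse the same 8 libraries, so the number cannot be set against that rate. The rate of peaks wider than 1500 bp per 1000 peaks was 0.765 in Foxa2-N3, which rests on 4 peaks, 2 of them adjacent on chromosome 19, against 0, 0 and 1 peaks in the other constructs with the DNA-binding domain of Foxa1 or Foxa2. It was 1.99 in Foxa3-C1 (15 peaks), where the other Foxa1 partner constructs had none; with others at or near 0, such rates stand apart easily. The share of peaks in the dense windows was 1.66% in Foxa3-C1, far above the other Foxa1 partner constructs. The median width of 462 bp in Foxa2-C3 stood apart from the 413 to 417 bp of the other constructs with the Foxa3 C-terminal domain.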

How the results depend on the processing

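The regions specific to one side and their equal list lengths, the correction for list length and the runs on the dense windows were added after the data were seen. No list held peaks on chromosome Y, the mitochondrial genome or unplaced sequence, so leaving those out changed nothing. Analyses that need gene positions were not run. No paired analysis by replicate number was possible because each construct has 1 library; pairs matched on construct design are in the report. Under the alternatives fixed in advance, 55 values of tests that could pass 0.05 kept their direction and side of the threshold, some with large moves given here; the adjusted similarity tests and the sign-flips could not pass it, so their side says nothing about stability. Leaving out 1 construct turned the sign of the width difference by DNA-binding domain (-15.8 to 35.8 bp; negative without Foxa1-N3 or Foxa3-C1), of that by partner (-15.25 to 34.1 bp; negative without Foxa1-N3 or Foxa2-C3) and of the similarity by partner (-0.0232 to 0.00739; positive without Foxa1-C3 or Foxa3-C2). The width difference by terminal layout ran from -67.9 to -18.6 bp and passed an unadjusted 0.05 without Foxa3-C1. The similarity by terminal layout ran from 0.0523 to 0.0989 and was the highest of 35 splits in 5 of the 8 runs and the second highest in the other 3 (without Foxa1-N3, Foxa3-C1 or Foxa3-C2). It was 0.0807 with reciprocal overlap, 0.0593 with all peaks and 0.0747 with the strongest 478. Leaving out 1 construct, the log2 difference in peak number ran from -1.87 to -0.87 by terminal layout, from 0.12 to 1.41 by DNA-binding domain (lowest without Foxa1-N3) and from 0.31 to 1.39 by partner, none under 0.05; by terminal layout it was -2.14 with peaks above the pooled median score. Peaks above the pooled median score gave a median index of 0.233 and shared shares of 68.5% (Foxa1-C3, Foxa3-N1), 64.9% (Foxa2-C3, Foxa3-N2), 96.2% (Foxa1-N3, Foxa3-C1), 69.6% (Foxa2-N3, Foxa3-C2) and 89.7% (Foxa3-C1, Foxa3-C2). Reciprocal 50% overlap, a stricter criterion, gave 65.5%, 63.5%, 64.5% and 76.3% for the last 4 of these pairs, all below the main values. The largest fall, from 90.5%, was in Foxa1-N3 and Foxa3-C1, whose median widths were 307 and 455 bp. Peaks of unequal width can fail this criterion, which was not separated from poorer overlap. With equal list lengths and without Foxa1-N3, regions specific to one side numbered 30 by DNA-binding domain and 37 by partner, against 14 and 19. The side of Foxa1-N3 then held fewer lists, so presence in fewer lists was enough to count, which was not separated from the change in list length. By terminal layout, regions specific to one side numbered 41 with the 956 strongest peaks of 8 lists, against 310, because fewer peaks enter. With all peaks and without Foxa1-N3 they numbered 392. Unknown depth limits every comparison of peak numbers, and a peak missing from a short list does not show that the site was unbound.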

Other observations

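The tests in this part were chosen after the data were seen.

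Sites bound by every construct also differed in how they were ranked. Over the 529 regions present in all 8 lists, Spearman's rho between the scores of 2 libraries, a correlation across regions that are not independent replicates, averaged 0.574 in pairs with the same terminal layout and 0.417 in the others. The difference of 0.156 was the largest of the 35 splits (highest other 0.112; exact permutation p = 0.0286, adjusted p = 0.0857 over 3 factors). For pairs with the same class of DNA-binding domain the means were 0.473 and 0.493. These values suggest, as a hypothesis, that the terminal layout or the antibody tied to it goes with the relative strength of common sites as well as with the choice of sites.

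The count of regions in all lists of one terminal side and in none of the other, 310 in both directions together, was reached by 1 of the 35 splits, the real one, and the highest other split gave 241, but chance cannot be excluded after adjustment over 3 factors (exact permutation p = 0.0857). With all peaks and without Foxa1-N3, 3 of the 35 splits gave as many (392; highest other 599). With the 956 strongest peaks of all 8 lists the count was 41 against 18 for the highest other split. With the 3594 strongest peaks and without Foxa1-N3 it was 234 against 222.

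Chromosome X carried fewer peaks for its length than the autosomes in all 8 lists, with a density of 0.197 (Foxa3-C2) to 0.351 (Foxa3-N2) times that of the autosomes; chromosome lengths were taken as the furthest peak end in any list.

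In the window of chromosome 13 from 23 to 24 Mb, Foxa3-C1 had 30 peaks, Foxa3-N2 23, Foxa3-C2 19, Foxa2-N3 12, Foxa2-C3 11, Foxa3-N1 3, Foxa1-C3 1 and Foxa1-N3 0. The window of chromosome 3 from 96 to 97 Mb held 23 peaks of Foxa3-C1, 17 of Foxa3-N2, 13 of Foxa2-C3, 10 of Foxa3-C2, 7 of Foxa2-N3, 1 of Foxa3-N1 and 0 of Foxa1-C3 and Foxa1-N3.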
